A study of Mus musculus with 8 samples.

How the data were processed

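RNA was measured in B220+CD3+ cells sorted from the spleens of Faslpr and Eaf2-deficient Faslpr mice. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with a dual-mode mRNA kit for DNBSEQ sequencing. Groups and replicate numbers came from the sample titles and genotype labels, 4 libraries labelled Eaf2KO_Faslpr and 4 labelled Faslpr. The deposited table held 17384 genes, with the authors' estimated counts (RSEM expected counts, not scaled to depth) and FPKM values per library. Per the submitters' processing notes, the tools were HISAT2 2.2.1, Bowtie2 2.4.5 and RSEM 1.3.1 on build GRCm39, with no role or order stated. The annotation, the filters and the strand setting are not given in the sources used here. Of the deposited estimated counts, 36.8% were whole numbers within 0.001. RSEM divides reads that match several genes by estimate, so values of near-identical copies, overlapping genes and antisense partners are uncertain.

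The estimated counts were rounded to whole numbers for the tests. The authors' FPKM values were used only to derive an effective gene length, from the ratio of estimated count to FPKM. The authors' means per group of the estimated counts came in 2 sets, and the second equalled the mean of replicates 1 to 3, without replicate 4, within 3.49e-10 reads. That observation gave the added setting without both replicates numbered 4. A further 16 per-sample columns of the authors' values, TPM and normalised read counts, were not used.

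Genes were kept by edgeR's filterByExpr, which left 12340, and libraries were scaled with TMM factors. Differences were tested with edgeR's quasi-likelihood test (glmQLFit and glmQLFTest, edgeR 4.0.16 in R 4.3.3) with Benjamini-Hochberg adjustment, over all 8 libraries and with no covariate or block. Each adjusted p for a gene comes from this test unless another tool is named, and a gene passed at an adjusted p under 0.05. Log2 fold changes are Eaf2KO_Faslpr over Faslpr. Standard errors were the absolute log2 fold change divided by the square root of the F statistic. CPM values are counts per megaread (M) of the tested genes after TMM scaling, given as mean ± SD (n = 4). Eaf2 was also tested with an exact two-sided permutation test of its CPM. Where a group had no reads, a fold was given only as a lower bound against a floor of 3 counts per library, and floors cover counting error only.

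In all, 32 gene lists were fixed before the data were examined, as were the main tests, most other settings tried and the naming rule. Several tests of explanations were chosen after the results were seen, among them clustering along chromosomes and the search for gene copies. The lists were pro-apoptotic, anti-apoptotic, death receptor and p53 target genes; NF-kB, immediate early, PI3K and AKT, and interferon-stimulated genes; T cell identity, CD4 and CD8, checkpoint, cytotoxic, cytokine and homing genes; proliferation, unfolded protein, heat shock, glycolysis and hypoxia, nuclear respiratory chain and elongation genes; mitochondrially encoded, ribosomal protein and replication-dependent histone genes. Markers of B cells, MHC class II presentation, antibody-secreting cells, macrophages, neutrophils, dendritic cells, erythroid cells and platelets, and stroma made up the other cell types, and the last list held genes flanking Eaf2. Of these, 31 had at least 3 tested members and went into limma's camera test on voom values (limma 3.58.1) with a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 31 lists. Counts of passing members were taken over all genes tested and also adjusted over the list alone. Some genes stood in more than 1 list: Fasl, Tnf, Tnfaip3, Birc3, Pmaip1, Bax, Bbc3, Btg2, Ifng, Gsk3b, Tnfrsf10b and Xbp1. The B cell list shared no gene with another list, and its 18 tested members also had reads in the Faslpr group.

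Named genes followed a rule. It took Eaf2 and Fas. In each direction it took the 6 genes with the largest change among those that passed, averaged at least 5 CPM and did not overlap between groups, leaving out predicted genes and receptor segments, of which the table held 2. It took up to 2 passing members of each list by smallest p (up to 3 for the apoptosis lists), the most abundant member of each list of other cell types, and up to 6 passing genes flanking Eaf2. Some genes it took are not reported here. Named after their values were seen were Tnfrsf21, Tnfrsf25, Ccng1, Fos, Klf4, Egr1, Nr4a3, Pik3r1, Tsc1, Pik3cg, Oas2, Cd6, Cd4, Zbtb7b, Runx3, Ctla4, Tox2, Pdcd1, Prf1, Il12rb1, Il21r, S1pr1, Atf4, Ddit3, Hsp90b1, Lyz2, Ell3, Golgb1, Naip1, Naip6, Hmga1 and Xlr3c, as were the members given as values that did not pass (Mcl1, Casp8, Fadd, Cdkn1a, Mdm2, Rela, Nfkb1, Isg15, Hspa1b, Cd3e, Cd3d, Eaf1 and the Bcl2a1 copies).

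Chromosomes and neighbours were looked up in the gene table of the GRCm38.p6 assembly by Entrez gene number, which matched 12253 of the 12340 tested genes. The assembly differs from the authors' GRCm39, so no coordinates are given. Near-identical copies of the 49 passing genes with an absolute log2 fold change of at least 3 were searched with BLAST 2.17.0 among GENCODE mouse transcripts of GRCm38, at 95% identity or more over at least 200 bases; 48 had a transcript sequence. Clustering of changed genes along chromosomes was tested with 10000 permutations of gene order (seed 1). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

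Estimated reads per library were 15.6 M, 18.3 M, 17.9 M and 18.2 M for Eaf2KO_Faslpr replicates 1 to 4 and 17.7 M, 16.8 M, 18.2 M and 18.6 M for Faslpr replicates 1 to 4. The floor of 3 counts lay between 0.161 and 0.193 CPM. The first principal component of log2 CPM held 52.8% of the variance and separated the genotypes.

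The scripts were tested on simulated data, with counts for the 12340 genes drawn from the real means and library sizes and 200 genes changed. edgeR recovered 55.2% of 67 genes changed 1.5-fold, 85.1% of 67 changed 2-fold and 95.5% of 66 changed 4-fold, with 6.11% false calls. DESeq2 recovered 67.2%, 88.1% and 97.0% with 19.7% false calls, and limma-voom 52.2%, 86.6% and 97.0% with 5.59%. A simulated rise of the NF-kB list was called by camera with the preset correlation (adjusted p = 9.94e-32), with an estimated correlation (adjusted p = 0.00146) and by fry (adjusted p = 5.47e-05, with 1 other list called). Each gene was drawn independently, so the simulation does not show how these set tests behave when genes of a list are correlated. The neighbour test gave a share of 0.5 for scattered genes and 1e-04 for simulated runs.

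Other settings chosen in advance were RLE and upper quartile scaling, no filter beyond 1 count in total, a mean of at least 5 CPM, the DESeq2 Wald test (DESeq2 1.42.0), limma-voom without and with sample quality weights, the replicate number as a block, receptor segments left out, each library left out in turn, and for lists an estimated correlation and fry. Added after the data were seen were the setting without both replicates numbered 4 and a B cell marker score (mean standardised log2 CPM of the B cell list) as a covariate. An alternative planned for tables without counts was not needed. Other splits of the libraries into 4 and 4, 35 with the real one, were refitted for the counts of genes and lists.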

Results

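Gene expression was measured by RNA sequencing in sorted B220+CD3+ spleen cells of Faslpr mice with and without Eaf2. Faslpr mice carry the lpr insertion in Fas, the gene of a death receptor, and accumulate T cells that stain for the B cell isoform of CD45. Eaf2 encodes a factor associated with the ELL transcription elongation proteins. The series held 8 libraries, 4 labelled Eaf2KO_Faslpr and 4 labelled Faslpr. Estimated reads per library ranged from 15.6 M to 18.6 M (M, megareads), and a floor of 3 reads corresponded to between 0.161 and 0.193 CPM, counts per megaread. The labels did not say whether replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical. Replicates of a group differed by more than sampling noise, with chi-square values per degree of freedom between 9.46 and 36.7.

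The comparison asked which apoptosis signalling genes differed between Eaf2KO_Faslpr and Faslpr cells. Within the apoptosis lists, Fasl was 1.74-fold lower (191 ± 13.5 against 332 ± 24.1 CPM, mean ± SD, n = 4) and Bcl2 was 1.46-fold lower (101 ± 10.9 against 147 ± 8.52 CPM), whereas Tnfaip3 was 2.92-fold higher and Tnf 4.56-fold higher. Tnfaip3 also stands in the NF-kB list. None of the pro-apoptotic, anti-apoptotic, death receptor and p53 target lists passed the main set test (limma camera, adjusted p = 0.769, 0.615, 0.0919 and 0.580). Of 24 immediate early genes 13 rose and 1 fell, with Jun (62.7-fold), Dusp1 (9.67-fold) and Junb (3.02-fold) among those that rose, and of 17 NF-kB genes 10 rose, among them Nfkbia (2.64-fold). In the same libraries 16 of 18 B cell markers and 8 of 10 MHC class II genes rose, by 3.49-fold and 3.07-fold at the list medians. The set tests of the immediate early, NF-kB, B cell and MHC class II lists passed with a preset inter-gene correlation and did not with an estimated one (limma camera, adjusted p = 0.357 for each).

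Eaf2 itself was measured at 4.74 ± 1.05 CPM in Eaf2KO_Faslpr and 25.5 ± 4.5 CPM in Faslpr cells (SD, n = 4 each), a log2 fold change of −2.43 (SE 0.18). The adjusted p was 2.9e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The highest Eaf2KO_Faslpr library, at 6.29 CPM, lay below the lowest Faslpr library, at 20.7 CPM, and the exact two-sided permutation test over 70 orderings gave p = 0.0286, the smallest it allows. Between 69.3 and 113.82 estimated Eaf2 reads remained per Eaf2KO_Faslpr library, 18.5% of the Faslpr level, and which part of the gene was deleted is not given in the sources used here. Fas was measured at 64.2 ± 6.87 against 54.3 ± 9.82 CPM (log2 fold change 0.24, adjusted p = 0.276), and passed in 1 of the 8 leave-one-out fits, without Faslpr replicate 4 (adjusted p = 0.0415).

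**Figure D1:**
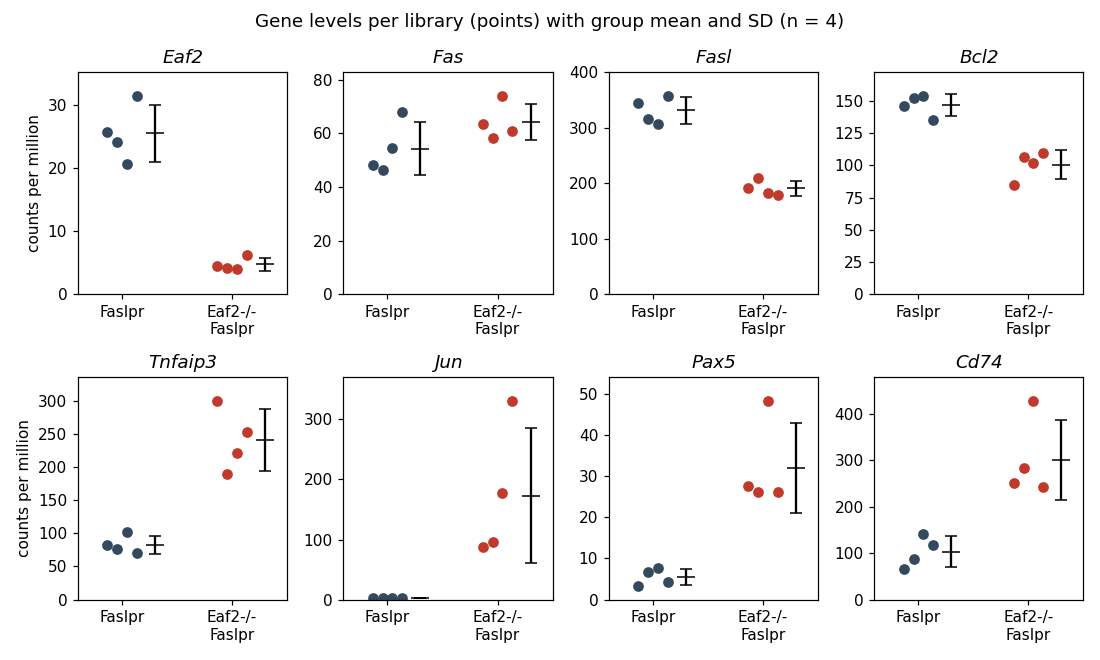
CPM of Eaf2, Fas, Fasl, Bcl2, Tnfaip3, Jun, Pax5 and Cd74 in each library, on linear axes from 0; points are libraries, and lines and bars give the mean ± SD of each group (n = 4). Eaf2 lies at or below 6.29 CPM in the Eaf2KO_Faslpr libraries and at or above 20.7 CPM in the Faslpr libraries, and the highest Pax5 point, 48.3 CPM, is Eaf2KO_Faslpr replicate 3.

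Of 12340 genes tested, 1493 (12.1%) changed at an adjusted p under 0.05, 881 of them higher and 612 lower in Eaf2KO_Faslpr cells. The median fold was 2.22 among the higher and 1.51 among the lower genes, and 678 genes changed at least 2-fold, 507 higher and 171 lower. CPM values of the groups did not overlap for 2180 tested genes (17.7%), where chance gives 2.86%. Without Faslpr replicate 2, 990 genes passed and 372 of them were lower. Without Eaf2KO_Faslpr replicate 3, the library with the most B cell and neutrophil transcripts, 1106 genes passed, 1050 of them among the 1493.

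Several genes were near off in one genotype. Arhgap31 was 112-fold higher in Eaf2KO_Faslpr cells (38.8 ± 7.74 against 0.337 ± 0.147 CPM), the peptide transporter Slc15a2 38.2-fold (23.3 ± 19.2 against 0.605 ± 0.0735 CPM; log2 fold change 5.25, and 4.51 without Eaf2KO_Faslpr replicate 3) and Acsf2 32.1-fold. The AP-1 subunit Jun rose from 2.74 ± 0.608 to 173 ± 113 CPM. Naip5, an inflammasome sensor, rose 11.4-fold, and summed with its near-identical copies Naip1 and Naip6 the level was 24.1 ± 5.55 against 2.15 ± 0.316 CPM. Hmga1b had no reads in the Faslpr libraries and 68.0 ± 14.3 CPM in the Eaf2KO_Faslpr libraries, at least 401-fold higher against a floor of 3 counts per library. It shares 99.8% identity with Hmga1, and the summed level of both was 153 ± 24.9 against 149 ± 18.5 CPM, so the Hmga1b value is uncertain. In the other direction the somatostatin receptor Sstr2 fell 51.4-fold (0.786 ± 0.599 against 39.6 ± 5.12 CPM), Enpp6 45.8-fold, Basp1 30.0-fold (3.32 ± 0.407 against 99.2 ± 6.90 CPM), Dlc1 16.2-fold, Islr2 9.45-fold and Tecta 7.52-fold. These 12 genes passed in each of the 8 fits that left out 1 library.

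**Figure D2:**
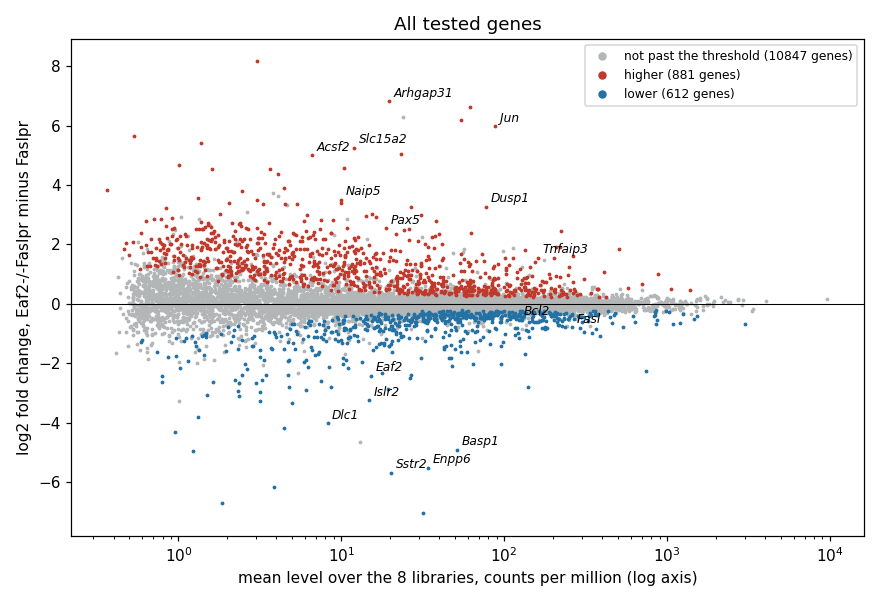
Log2 fold change (Eaf2KO_Faslpr over Faslpr) of each tested gene against its mean CPM over 8 libraries, on a log axis; 881 genes passed as higher, 612 as lower and 10847 did not pass. The 2 genes past the threshold with a group at 0 reads, Hmga1b and Xlr3c, are not drawn.

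B cell markers rose more than any other tested list with a called set test. Over all genes tested, 16 of 18 members rose and none fell, and the counts were 16 and 0 adjusted over the list alone (camera adjusted p = 2.47e-11, and adjusted p = 0.357 with an estimated correlation). Pax5, the B lineage transcription factor, reached 32.0 ± 10.9 against 5.5 ± 2.03 CPM (5.82-fold) and the inhibitory receptor Cd22 66.9 ± 15.9 against 16.7 ± 5.25 CPM. Pou2af1, the most abundant member, did not pass (1017 ± 98.4 against 1154 ± 118 CPM), and held most of the summed level of the list, 1694 ± 245 against 1485 ± 92.1 CPM. MHC class II genes rose in 8 of 10 members, also 8 adjusted over the list alone (camera adjusted p = 5.28e-08, and adjusted p = 0.357 with an estimated correlation), with Ciita, the class II transactivator, 3.92-fold, H2-Oa 4.95-fold and Cd74 2.91-fold higher (301 ± 86.1 against 103 ± 33.7 CPM). Ciita lies on chromosome 16, as Eaf2 does, and a difference of genetic background there was not tested for it. Without Eaf2KO_Faslpr replicate 3, which had the highest Pax5 level (48.3 CPM), 14 B cell markers and 8 MHC class II genes still rose. A B cell marker score added as a covariate after the data were seen left 21 of the genes tested past the threshold, and Eaf2 itself did not pass (log2 fold change −1.92, adjusted p = 0.130). Of the variance of that score, 83.3% lay between the groups.

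Markers of other cell types moved less evenly. Macrophage genes rose in 3 of 12 members, 4 adjusted over the list alone (camera adjusted p = 0.0734, 0.00194 without Eaf2KO_Faslpr replicate 4 and 0.00630 with the replicate number as a block): among them Cybb 2.74-fold and Lyz2 7.69-fold, the latter without a call in 3 leave-one-out fits, without Faslpr replicates 1, 2 or 4 (adjusted p up to 0.112) and with a log2 fold change of 1.37 without Eaf2KO_Faslpr replicate 3 against 2.94, while Cd68 was at 27.2 ± 3.70 against 32.0 ± 5.56 CPM. By edgeR 0 of 6 neutrophil genes passed over all genes tested, with 5 at an unadjusted p under 0.05, 3 passing by DESeq2, 0 by limma-voom and 5 adjusted over the list alone (camera adjusted p = 0.198, and 0.0106 with the replicate number as a block). Their summed level was 122 CPM in Eaf2KO_Faslpr replicate 3 and between 14.1 and 20.9 CPM in the other 7 libraries, and 3 genes passed without Eaf2KO_Faslpr replicate 1 and 4 without Eaf2KO_Faslpr replicate 2. In the antibody-secreting cell list, Xbp1 fell 1.40-fold, 1 of 11 members by either adjustment (over all genes tested and adjusted over the list alone), and Sdc1 was at 365 ± 31.8 against 439 ± 43.9 CPM, passing without Faslpr replicate 3 (adjusted p = 0.0379) and by DESeq2 (adjusted p = 0.0450) but not by edgeR over all libraries (adjusted p = 0.0912). Of the remaining lists, 1 of 6 dendritic (Ccr9, lost in 5 of 8 leave-one-out fits, adjusted p up to 0.0684), 1 of 7 erythroid and platelet (Car2, 1.90-fold) and 2 of 4 stromal and endothelial genes (Col1a1 2.31-fold, Pecam1 1.82-fold) rose over all genes tested and adjusted over the list alone. Their camera adjusted p were 0.580, 0.580 and 0.193, and that of the antibody-secreting cell list 0.393. The erythroid and platelet list had a median log2 fold change of −0.18 and a mean of −0.10 against an upward camera direction. Tcf4, the most abundant dendritic member, was at 38.1 ± 4.75 against 30.3 ± 10.6 CPM, and Cxcr2, the most abundant neutrophil member, at 11.4 ± 1.68 against 12.5 ± 1.96 CPM.

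Most core apoptosis genes gave no call. Among pro-apoptotic BCL2 family members and executioners, 1 of 22 rose and 1 fell, over all genes tested and adjusted over the list alone (camera adjusted p = 0.769). Pmaip1, which encodes the BH3-only protein NOXA, rose 1.86-fold (52.9 ± 14.8 against 28.4 ± 5.30 CPM), with an adjusted p of 0.0827 when both replicates numbered 4 were left out, a setting added after the data were seen. Without Faslpr replicate 4, 2 of the list rose, without Faslpr replicate 3, 2 fell, and without Eaf2KO_Faslpr replicate 3 none fell. The list's median log2 fold change was 0.0011, its mean −0.0079 and its camera direction down. Among anti-apoptotic genes, 1 of 15 rose and 2 fell over all genes tested, and 2 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.615). The survival gene Bcl2 fell with an adjusted p of 0.0031, Bcl2l2 fell 1.84-fold but lost its call in 6 of 8 leave-one-out fits (adjusted p up to 0.104), and Birc3, an inhibitor of apoptosis and NF-kB target, rose 1.33-fold. Without Eaf2KO_Faslpr replicate 1 or Faslpr replicate 4, 2 of these genes rose. Values of Bcl2a1a, Bcl2a1b and Bcl2a1d, near-identical copies that may share reads, did not pass. Mcl1 had a log2 fold change of 0.01 (adjusted p = 0.961).

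In the death receptor list 4 of 18 members rose and 1 fell, over all genes tested and adjusted over the list alone (camera adjusted p = 0.0919, and 0.0452 without Eaf2KO_Faslpr replicate 2). Fasl, the Fas ligand, fell with an adjusted p of 0.000198. The deubiquitinase Tnfaip3 (A20), an inhibitor of NF-kB signalling, rose from 82.4 ± 13.5 to 241 ± 47.0 CPM, and Tnf from 2.48 ± 0.566 to 11.3 ± 3.50 CPM. The receptors Tnfrsf21 and Tnfrsf25, named after their values were seen, rose 3.63-fold and 3.64-fold from levels of 0.370 and 0.521 CPM, and Tnfrsf25 lost its call in 6 of 8 leave-one-out fits (adjusted p up to 0.0830). Casp8 and Fadd, which carry the signal of the receptors, had log2 fold changes of 0.03 and 0.02 and did not pass. Among p53 and its targets 3 of 22 rose and 1 fell over all genes tested, and 3 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.580). The polo-like kinases Plk2 and Plk3 rose 3.14-fold and 2.56-fold beside Pmaip1. Ccng1 fell 1.35-fold and lost its call in 5 of 8 leave-one-out fits (adjusted p up to 0.0871), and the targets Cdkn1a and Mdm2 had log2 fold changes of −0.07 and 0.09 and did not pass. B cell markers rose in the same libraries as these lists.

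Immediate early genes, which answer receptor signalling and also cell handling, rose in 13 of 24 members, and 1 fell, over all genes tested; adjusted over the list alone 14 rose and 2 fell (camera adjusted p = 5.28e-08, and adjusted p = 0.357 with an estimated correlation). Dusp1, a phosphatase of MAP kinases, rose from 14.5 ± 1.93 to 141 ± 40.4 CPM and Junb from 133 ± 18.7 to 400.1 ± 49.4 CPM. Fos rose 5.42-fold and Klf4 5.67-fold, whereas Egr1, of the same list, was at 407 ± 50.4 against 413 ± 98.1 CPM. Nr4a3 fell 1.46-fold and lost its call in 5 of 8 leave-one-out fits (adjusted p up to 0.0765). The NF-kB list had 10 of 17 members higher and none lower, over all genes tested and adjusted over the list alone (camera adjusted p = 1.59e-05, and adjusted p = 0.357 with an estimated correlation). Nfkbia and Tnfaip3, both feedback inhibitors of the pathway, had the smallest p of the list, with Nfkbia at 224 ± 44.0 against 85.0 ± 11 CPM, while the subunits Rela and Nfkb1 had log2 fold changes of −0.10 and −0.12 and did not pass. Without Faslpr replicate 2, 6 NF-kB genes passed. B cell markers, which rose 3.49-fold at the median, rose in the same libraries as these lists, and no immediate early gene that had passed did so with the B cell score as a covariate, at a median log2 fold change of these 13 genes of 1.58 against 1.59 (median SE 0.374 against 0.147). The set tests of both lists passed with the score (adjusted p = 6.71e-06 and 0.00224). In other splits of the 8 libraries into groups of 4, between 2 and 13 lists passed the camera test, against 7 for the genotypes.

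**Figure D3:**
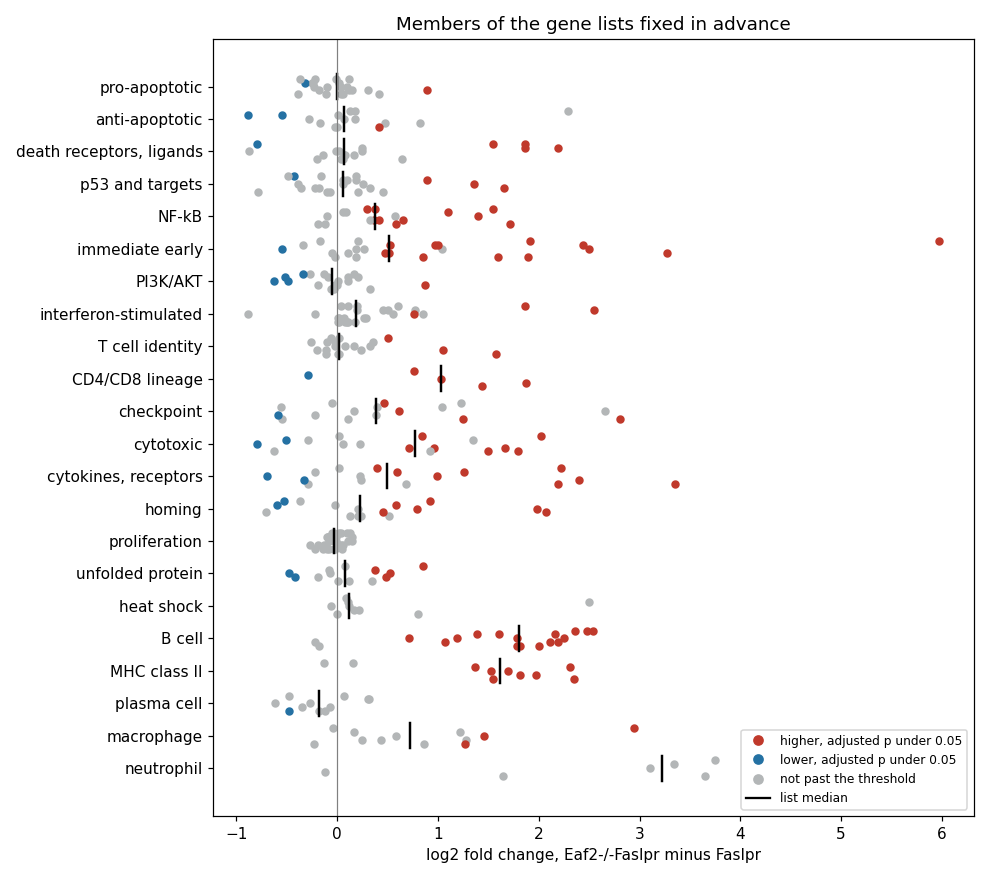
Log2 fold change (Eaf2KO_Faslpr over Faslpr) of the tested members of 22 gene lists; points are genes coloured by whether they rose, fell or did not pass, and bars mark list medians. The B cell median lies at 1.80, the MHC class II median at 1.62 and the proliferation median at −0.03.

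PI3K, AKT and mTOR pathway components had 1 of 21 members higher and 4 lower, over all genes tested and adjusted over the list alone (camera adjusted p = 0.286). The catalytic subunit Pik3cd rose 1.83-fold (246 ± 29.4 against 135 ± 26.7 CPM), and Pik3r1, Tsc1 and Pik3cg were among those that fell. Without Faslpr replicate 2, 2 of the list fell and Tsc1 had no call (adjusted p = 0.0555), and Pik3cg lost its call in 5 of 8 leave-one-out fits (adjusted p up to 0.0854). Of 26 interferon-stimulated genes 3 rose and none fell, over all genes tested and adjusted over the list alone (camera adjusted p = 0.00775, and adjusted p = 0.714 with an estimated correlation), and the set test did not pass without Faslpr replicate 1 (adjusted p = 0.127), by fry (adjusted p = 0.180) or with the B cell score (adjusted p = 0.382). They were Trim30a (1.69-fold, 214 ± 11.4 against 126 ± 11.5 CPM), Ifi44 (5.85-fold) and Oas2 (3.64-fold), the latter pair under 5 CPM in both groups, while Isg15 had a log2 fold change of 0.28 and did not pass. B cell and MHC class II genes rose in the same libraries as these lists.

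In the list of T cell receptor complex and T lineage genes, 3 of 19 members rose and none fell over all genes tested, and 4 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.260). Gata3, a T helper lineage factor, rose 2.98-fold from 1.85 ± 0.549 CPM, the adhesion receptor Cd2 rose 2.07-fold and Cd6 1.42-fold, while Cd3e and Cd3d had log2 fold changes of −0.11 and 0.01 and did not pass. Without Faslpr replicate 4, 5 members of this list rose, and without Faslpr replicate 3, 1 fell. Coreceptor and lineage genes changed in 5 of 5 members, 4 higher and 1 lower, over all genes tested and adjusted over the list alone (camera adjusted p = 0.0316, and adjusted p = 0.38 with an estimated correlation and 0.174 with the B cell score). Cd8a rose 3.66-fold (20.7 ± 5.29 against 5.63 ± 2.64 CPM), Cd8b1 2.04-fold, Cd4 2.71-fold (98.4 ± 31.7 against 36.3 ± 14.0 CPM) and Zbtb7b 1.69-fold, the last without a call in 5 of 8 leave-one-out fits (adjusted p up to 0.0785), and Runx3 fell 1.22-fold. B cell and MHC class II genes rose in the same libraries as these T cell genes. The share of cells bearing CD4 or CD8 among those sorted was not measured here.

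Among inhibitory receptors and factors of chronically stimulated T cells, 4 of 16 members rose and 1 fell over all genes tested, and 8 rose and 4 fell adjusted over the list alone (camera adjusted p = 0.0919, and 0.0439 without Eaf2KO_Faslpr replicate 2). The inhibitory receptor Btla rose 2.37-fold (204 ± 23.1 against 86.0 ± 10.2 CPM) and Cd200 1.52-fold, with Ctla4 and Tox2, whereas Pdcd1, the gene of PD-1, fell 1.5-fold (119 ± 7.88 against 179 ± 14.4 CPM). Btla and Cd200 lie on chromosome 16, as Eaf2 does, and a difference of genetic background there was not tested for them. Without Faslpr replicate 1, 2 members rose, and without Eaf2KO_Faslpr replicate 1, 3 fell; Tox2 lost its call without Faslpr replicates 1, 2 or 4 and Ctla4 without Eaf2KO_Faslpr replicate 3 or Faslpr replicate 1 (adjusted p up to 0.0641 and 0.0549). Cytotoxic and NK receptor genes had 7 of 16 members higher and 2 lower, over all genes tested and adjusted over the list alone (camera adjusted p = 0.147): Gzmk rose 1.64-fold (167 ± 33.9 against 102 ± 15.6 CPM), and Prf1, the gene of perforin, fell 1.42-fold beside Fasl. In leave-one-out fits 4 rose without Eaf2KO_Faslpr replicate 3 and 3 without Faslpr replicate 1 or Faslpr replicate 2, and Prf1 did not pass without the latter (adjusted p = 0.0502). The set test passed without Eaf2KO_Faslpr replicate 2 or 4 or Faslpr replicate 4 (adjusted p = 0.0452, 0.0263 and 0.0279). B cell markers, 16 of 18 of them higher and 3.49-fold at the median, rose in the same libraries as these lists.

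Cytokine and cytokine receptor genes had 8 of 16 members higher and 2 lower over all genes tested, and 9 and 2 adjusted over the list alone (camera adjusted p = 0.0160, and adjusted p = 0.357 with an estimated correlation and 0.0696 with the B cell score). The receptor gene Il7r rose 5.29-fold (11.5 ± 3.94 against 2.16 ± 1.21 CPM) beside Tnf, while Il12rb1 fell 1.63-fold and Il21r 1.25-fold, the latter without a call in 6 of 8 leave-one-out fits (adjusted p up to 0.106). Without Faslpr replicate 2, 4 members rose. Among homing and adhesion genes, 6 of 16 rose and 2 fell over all genes tested, and 7 rose and 4 fell adjusted over the list alone (camera adjusted p = 0.0919). The follicle homing receptor Cxcr5 fell 1.52-fold (240 ± 22.2 against 364 ± 19.7 CPM) with S1pr1, the receptor for exit from lymphoid organs, and the integrin gene Itgae rose 4.19-fold from 0.725 ± 0.346 CPM. Without Eaf2KO_Faslpr replicate 2, 4 homing genes fell. B cell markers rose in the same libraries as these lists.

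DNA replication and mitosis genes gave 0 calls among 32 by edgeR, over all genes tested and adjusted over the list alone, with 0 at an unadjusted p under 0.05 and 0 by DESeq2 or limma-voom (camera adjusted p = 0.580, and 0.0169 without Eaf2KO_Faslpr replicate 1). In the unfolded protein list 4 of 13 rose and 2 fell, over all genes tested and adjusted over the list alone (camera adjusted p = 0.264). Dnajb9 rose 1.81-fold and the chaperone Hspa5 1.44-fold (682 ± 34.4 against 473 ± 36.2 CPM), with Atf4 and Ddit3, which encode transcription factors of the stress response, while Xbp1 and Hsp90b1 fell. Ddit3 lost its call in 5 of 8 leave-one-out fits (adjusted p up to 0.117) and Atf4 without Eaf2KO_Faslpr replicates 3 or 4 or Faslpr replicate 1 (adjusted p up to 0.0558). Without Eaf2KO_Faslpr replicate 3, Eaf2KO_Faslpr replicate 4 or Faslpr replicate 1, 2 rose. In the same libraries as these unfolded protein genes, B cell markers rose. By edgeR 0 of 9 heat shock genes passed by either adjustment, over all genes tested or adjusted over the list alone, with 3 at an unadjusted p under 0.05, 1 passing by DESeq2 and 0 by limma-voom (camera adjusted p = 0.147, and 0.0460 without Eaf2KO_Faslpr replicate 2).

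Of 18 glycolysis and hypoxia genes, Hk2 alone rose, 1.79-fold, over all genes tested and adjusted over the list alone (camera adjusted p = 0.958), without a call when Eaf2KO_Faslpr replicates 1 or 2 or Faslpr replicates 2 or 4 was left out (adjusted p up to 0.0778). Of 35 nuclear respiratory chain genes, Sdha rose 1.16-fold over all genes tested (adjusted p = 0.0490), with none adjusted over the list alone (camera adjusted p = 0.917), and lost its call in 8 of 8 leave-one-out fits (adjusted p up to 0.141). Among 21 elongation factors, the group Eaf2 belongs to, 2 rose and 1 fell, over all genes tested and adjusted over the list alone (camera adjusted p = 0.701): Hexim1, an inhibitor of the elongation kinase P-TEFb, rose 1.39-fold (102 ± 3.96 against 73.7 ± 6.04 CPM), Ell3 rose 2.2-fold, and Aff1, a scaffold of the super elongation complex, fell 1.36-fold. Ell3 lost its call without Eaf2KO_Faslpr replicate 3 or Faslpr replicates 1, 2 or 4 (adjusted p up to 0.0702), and Aff1 without Faslpr replicate 2 (adjusted p = 0.0563). Their median log2 fold change was −0.05, the mean 0.0021 and the camera direction down. Eaf1, the closest relative of Eaf2, had a log2 fold change of 0.0048 and did not pass. The elongation genes that changed did so in libraries where B cell markers rose as well. Of 47 ribosomal protein genes Rpl30 rose 1.28-fold and Rps2 fell 1.41-fold, over all genes tested and adjusted over the list alone (camera adjusted p = 0.368, and 0.000682 without Faslpr replicate 4), and Rps2 shares reads with near-identical copies and lost its call without Eaf2KO_Faslpr replicate 4 (adjusted p = 0.0508). Of 4 tested replication-dependent histone genes, whose messages lack a poly(A) tail, H2bc8 rose from 0.197 ± 0.136 to 0.862 ± 0.313 CPM, over all genes tested and adjusted over the list alone (camera adjusted p = 0.532), and lost its call in 5 of 8 leave-one-out fits (adjusted p up to 0.0977). The list of 13 mitochondrially encoded transcripts was not analysed here.

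Genes beside Eaf2 on chromosome 16 changed in 7 of 34 members, 6 higher and 1 lower, over all genes tested and adjusted over the list alone (camera adjusted p = 0.0594, and 0.0333 with the replicate number as a block). Besides Arhgap31 and Slc15a2, B4galt4 rose 25.3-fold (1.95 ± 0.334 against 0.0690 ± 0.0692 CPM, the latter below the floor of 3 counts; log2 fold change 4.66, and 5.44 without Faslpr replicate 3), Iqcb1 1.65-fold, the costimulatory ligand Cd86 3.39-fold and Heg1 3.25-fold, and Golgb1, named after its value was seen, fell 1.18-fold. Golgb1 lost its call without Eaf2KO_Faslpr replicates 1, 2 or 3 or Faslpr replicate 2 (adjusted p up to 0.0723). The set test passed in 5 leave-one-out fits, without Eaf2KO_Faslpr replicates 2, 3 or 4 or Faslpr replicates 1 or 2, with adjusted p between 0.0170 and 0.0488. B cell markers rose in the same libraries. Chromosome and neighbours were taken from the GRCm38.p6 gene table.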

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

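The tests for a larger share of B cells, B cells as the whole source, a lower share of the main cell type, handling stress, chromosome stretches and gene copies were chosen only after the result was seen, and those for gene length and for calls kept with the B cell score after the rise was seen but before their own values were; the tests for a single library and other splits of the libraries were set before it. A value was picked where 1 of the 4 libraries of a group lay far from the rest, which chance does in about 5 percent of groups. Here 14 values stood apart in 206 groups (6.80%), so their number is close to what chance gives; 13 of them follow.

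Eaf2KO_Faslpr replicate 1 had the fewest estimated reads of its group, 15.6 M against 17.9 M to 18.3 M. It also had the highest Arhgap31 (50.4 CPM, next 35.7), Birc3 (75.9 CPM, next 69.7) and Btla (238 CPM, next 197). Eaf2KO_Faslpr replicate 3 had the highest Pax5 (48.3 CPM, next 27.6) and summed neutrophil level (122 CPM, next 20.9) and the lowest Aff1 (213 CPM, next 262) and summed PI3K and AKT level (3232 CPM, next 3506). Faslpr replicate 3 had the highest Plk3 (6.22 CPM, next 4.89) and Il7r (3.96 CPM, next 1.72). Faslpr replicate 4 had the lowest Aff1 (288 CPM, next 356) and the highest summed death receptor level (1153 CPM, next 1053) and cytotoxic level (1303 CPM, next 1122).

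The rise of B cell and MHC class II genes in cells gated for CD3 is the first pattern. A single library does not account for it: without Eaf2KO_Faslpr replicate 3, 14 of the 16 B cell markers still rose, with a median fold of 2.85. A lower share of the main cell type would raise the other types alike. It is argued against as the whole cause only for 4 lists chosen after the result was seen. Among members at or below 8.5 CPM in Faslpr, the median level of the B cell list, a small share could show. There median log2 fold changes were 1.82 for 9 B cell, 0.857 for 9 macrophage, 0.255 for 4 dendritic and −0.274 for 6 erythroid and platelet genes. The gap was 2.09 against a deviation of 0.584 around their own lists. Faslpr replicate 4 was the highest of its group in the erythroid and platelet list (mean log2 CPM 2.56, others 0.703 to 1.35). Lists outside that test had medians of 3.22 (neutrophil, highest in Eaf2KO_Faslpr replicate 3), 0.38 (stromal), 1.03 (CD4 and CD8) and −0.19 (antibody-secreting cells). A lower share as part of the cause stays open. A larger share of B cells, or of CD3-positive cells bound to them, may be the source, since 88.9% of 18 markers rose with an interquartile range of 0.945 in log2, among them Pax5 (32.0 against 5.5 CPM), as did Cd74 of the MHC class II list (301 against 103 CPM); the most abundant B cell marker, Pou2af1, did not (1017 against 1154 CPM). A change of expression within the B220+CD3+ cells of Eaf2-deficient mice, the biological explanation the design gives, was not separated from it and stays open.

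The rise of immediate early and NF-kB genes is the second. Removing a trend of fold change with gene length left the immediate early median at 0.54 from 0.52, so length is not the whole cause. Handling stress is not excluded: heat shock genes had a median log2 fold change of 0.11 (median absolute deviation 0.152, 0 of 9 passing by edgeR, 3 at an unadjusted p under 0.05, 1 by DESeq2, 0 by limma-voom) but a mean of 0.435, with Hspa1b at 1.62 against 0.280 CPM (adjusted p = 0.0732), and their set test passed without Eaf2KO_Faslpr replicate 2 (adjusted p = 0.0460) and with the B cell score (adjusted p = 0.0254). B cells as the whole source of the immediate early rise are not settled. By the measure set before its values were seen, a loss of most calls with the B cell score as a covariate would point to B cells. That outcome was met, since 0 of the 13 genes that had passed kept the call. It cannot decide the question, because the standard errors rose while the median log2 fold change of these genes hardly moved. A measure chosen after the result was seen went the other way. With the score the list's median was 0.51, and at least 0.342 with any 1 library left out. That of MHC class II genes, which are not in the score, went from 1.62 to 0.26. The second measure rests on the small part of the score's variance that lies within the groups. B cells as a source of part or all of the immediate early rise cannot be told apart from an effect within the sorted cells. The same holds for the NF-kB rise (median 0.38, and with the score 0.34, or 0.145 without Eaf2KO_Faslpr replicate 3). An effect of Eaf2 stays open and untested. The score follows the groups (83.3% of its variance), so the median standard error of the 13 immediate early genes went from 0.147 to 0.374. None of them kept its call, at a median log2 fold change of 1.58 against 1.59. The camera set tests of the immediate early and NF-kB lists passed with the score (adjusted p = 6.71e-06 and 0.00224) but not with an estimated correlation (adjusted p = 0.523 for both).

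The third is the set of genes near on or off in one genotype. A small share of an added cell type cannot lower a gene at least 8-fold, yet 17 genes fell that far, against 32 that rose that far. With no near-identical copy in the table, 12 fell and 23 rose that far. The falls say nothing on the loss of a part of the sorted cells, which was not tested for these genes. Reads moved between near-identical copies may account for 10 of 13 genes changed that far with a tested copy, Hmga1b among them. Their summed level changed less than 2-fold. Where an abundant copy holds most of a sum, it changes little whatever the gene does, so the count of 10 is no evidence of moved reads. Gm10420 and Gm6139, for example, share 1 sum with Rps2 (1440 against 1711 CPM), which alone held 1209 against 1708 CPM. Moved reads are argued against for the 72.9% (35 of 48) without a copy. Genetic background that differs along chromosome stretches, as around Eaf2 on chromosome 16 of GRCm38.p6, is a candidate explanation: 62 neighbouring pairs of genes fell together, where permuted gene orders gave a mean of 28.4 and at most 49 (share 1e-04, the smallest they can give), and genes that rose gave 99 against 59.5. Genes with an absolute log2 fold change of at least 3 also held more neighbouring pairs than permuted orders, 2 against a mean of 0.180 (share 0.014). Sstr2 fell with its neighbours Slc39a11 and Cog1, and Enpp6 with Irf2. Neighbours may also share regulation, so an effect of Eaf2 itself stays open for these genes.

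A chance division of these 8 libraries is argued against for the counts of genes. The genotypes gave 1493 changed, 881 higher, 612 lower and 678 at least 2-fold. Only 1 of 35 splits gave as many, the real one, which is the smallest share that 35 splits allow. The highest of the other splits gave 0 genes by edgeR, and these splits held 78 to 1238 genes at an unadjusted p under 0.05 against 3070. The other splits mix the genotypes, which widens the spread within their groups and lowers their calls. Chance differences between animals are not covered, since the replicates may be technical. Chance cannot be excluded for the count of lists: the genotypes gave 7, as many or more came from 19 of 35 splits, and the highest other split gave 13.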

How the results depend on the processing

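The settings without both replicates numbered 4 and with a B cell marker score as a covariate were chosen after the data were seen. Against 1493 genes changed, RLE and upper quartile scaling, no filter, DESeq2, limma-voom without and with quality weights and receptor segments left out gave between 1481 and 1955, with 1411 to 1493 of the calls shared, and no called gene changed sign under any of them. Eaf2 lay between −2.44 and −2.33 in log2 and passed. A filter at a mean of 5 CPM gave 576 genes higher and 331 at least 2-fold, with 9931 genes tested in place of 12340. Scaling moved the share of higher calls only between 59.0% and 60.0%.

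With 1 library left out, between 990 and 1599 genes changed, 618 to 940 higher, 372 to 659 lower and 538 to 760 at least 2-fold, Eaf2 lay between −2.60 and −2.31, and 7 to 12 lists passed. The low counts, 990 and 372, came without Faslpr replicate 2 and the 12 lists without Eaf2KO_Faslpr replicate 2, and the cause was not tested beyond there being fewer samples. Without both replicates numbered 4, 403 genes were lower and 15 lists passed, and the respiratory chain list passed upward (adjusted p = 0.00434, main 0.917); the cause was not tested. Of the 70 genes besides Eaf2 that the naming rule took, 8 lost their call in that setting (among them Pmaip1, Bcl2l2, Hk2, Sdha, H2bc8, Ccr9 and Car2).

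With the B cell score, 21 genes changed, 13 higher and 8 lower, and 21 changed at least 2-fold. Eaf2 was at −1.92 with an adjusted p of 0.130, against at most 0.000246 in the other settings. Of these 70 genes, 60 lost their call, and Fas, Pou2af1, Sdc1, Cd68, Cxcr2 and Tcf4 had had none to lose. Of the 1493 genes 86 had the opposite sign in that fit. Of the score's variance 83.3% lay between the groups, which leaves little to test. Set tests turned direction in that fit for proliferation (adjusted p = 4.02e-17) and neutrophil genes (adjusted p = 1.4e-05); the cause was not tested. Those of immediate early (adjusted p = 6.71e-06) and NF-kB genes (adjusted p = 0.00224) passed with the score, and those of B cell (adjusted p = 0.146) and MHC class II genes (adjusted p = 0.288) did not; heat shock (adjusted p = 0.0254), checkpoint (adjusted p = 0.00251), glycolysis and hypoxia (adjusted p = 0.00103) and Eaf2 flanking genes (adjusted p = 0.00210) passed with it. An estimated correlation left 0 lists by camera (3 at an unadjusted p under 0.05), against 7 with the preset one and 10 by fry. By fry the death receptor list, stromal genes and genes flanking Eaf2 passed (adjusted p = 0.00905 each), as did homing genes (adjusted p = 0.0251), and interferon-stimulated genes did not (adjusted p = 0.180).

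With the replicate number as a block, 1425 genes changed (1284 shared), 854 higher and 571 lower, 672 at least 2-fold, Eaf2 was at −2.43 and 10 lists passed, with macrophage, neutrophil and Eaf2 flanking genes added to the 7. Whether the numbers pair the samples stays open. Deviations of same-numbered libraries correlated at 0.128, 0.168, 0.0639 and −0.0501, against −0.255 to 0.163 for other pairs of libraries. Eaf2KO_Faslpr replicates 1 and 2 and Faslpr replicates 1, 2 and 3 correlated best with their own number, and the other libraries did not.

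Low genes limit precision: at a floor of 0.161 to 0.193 CPM, levels such as 0.197 CPM for H2bc8 rest on a few reads.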

Other observations

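The genes in this paragraph were chosen after their values were seen. The transcription factor gene Foxp3 rose from 0.666 ± 0.303 to 4.15 ± 1.53 CPM (log2 fold change 2.62, adjusted p = 0.00218), and the surface receptor gene Nrp1 from 1.72 ± 0.913 to 18.1 ± 2.08 CPM (log2 fold change 3.39). Il21 rose from 0.787 ± 0.585 to 8.23 ± 10.9 CPM but lost its call in 5 of 8 leave-one-out fits (adjusted p up to 0.111), with a log2 fold change of 1.81 without Eaf2KO_Faslpr replicate 1 against 3.35. Socs3, an inhibitor of cytokine signalling, rose from 3.38 ± 1.72 to 27.7 ± 15.0 CPM, and the kinase gene Sik1 from 5.05 ± 1.36 to 48.4 ± 6.46 CPM. In the other direction Dock9 fell from 1239 ± 60.6 to 256 ± 36.6 CPM (log2 fold change −2.28, adjusted p = 1.6e-06), and the homeobox gene Meis1 from 44.8 ± 30.5 to 8.51 ± 1.06 CPM. B cell markers rose in the same libraries as the genes that rose here, and the share of other cells among those sorted was not measured.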
